A study of Mus musculus with 10 samples.

How the data were processed

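Lung tumours were grown from cells of a mouse lung adenocarcinoma line injected into a vein of syngeneic mice, and tumour-bearing mice were treated for 11 days. Per the labels, Epcam+ cells were sorted from dissociated nodules for bulk RNA (total RNA, stranded libraries, paired reads of 150 bases, 3 SHP099 and 3 vehicle libraries). For single-cell RNA, live cells of 3 mice per treatment were hashtagged and pooled, giving 4 pools (vehicle, SHP099, SX682 and both drugs) made with a 10x V(D)J kit. The bulk counts are raw read counts per gene, deposited without normalization. Per the submitters' processing notes, reads were processed with STAR, Picard, HTSeq, DESeq2 and bedtools and R 3.3.0 on mm10; other versions are not given in the sources used here. Counting was unstranded per the file labels. The single-cell counts are raw UMI counts per gene and cell, deposited without normalization after Cell Ranger. The cluster number and the condition (treatment and hashtag replicate) of each cell, which are other columns than measurements, were made by the authors with iCellR and hashtag demultiplexing, with settings not given in the sources used here.

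The deposited matrix held 44986 cells with at least 500 UMIs and at most 20% mitochondrial UMIs. A separate table gave 6 clusters for 9540 neutrophils and another gave 9 clusters for 6570 T cells. Clusters carry no names. Each was named here from its 10 leading genes (at least 100 CPM, pseudocount of 10 CPM) and from fixed marker lists at a log2 fold of 1 or more, and CD8 clusters (T1, T2, T3, T5 and T9) by a ratio of Cd8 to Cd4 UMIs of at least 5. CPM of bulk libraries and of genes tested in sums were computed on TMM-scaled library sizes, and those used to name clusters, of keratins by cell type and of gut, lung and S100 genes in tumour cells on unscaled UMI totals.

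Gene tests used edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test, two-sided, a call at a Benjamini-Hochberg adjusted p below 0.05) with limma 3.58.1 under R 4.3.3. Single-cell counts were summed per mouse over cells of a class, for mice with at least 10 cells, with the 4 treatments in 1 fit; cells were not treated as replicates. The summed sets held 179 to 1373 neutrophils, 106 to 495 CD8 T cells and 57 to 1123 tumour cells per mouse. Shares of cells were tested by exact permutation of 12 mice between treatments (15400 partitions, smallest p 6.49e-05, F statistic on logit shares with 0.5 cells added), adjusted over classes or clusters, and by edgeR on cell counts per contrast. Gene lists (45, each with at least 3 measured genes) were tested by camera with a correlation of 0.01, camera with an estimated correlation, and fry; a list's genes were called over all genes and adjusted over the list alone. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Gene positions came from GENCODE vM21.

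Groups, tests, lists and the rule for named genes were fixed before the data were examined. The rule names, per comparison, up to 10 genes each way by fold change among genes that passed, were well expressed (3 log2 CPM in bulk, 5 in sums) and had groups that did not overlap. It adds up to 4 genes of each relevant list, and Ptpn11, Cxcr1, Cxcr2, Cxcl1, Cxcl2, Cxcl3 and Cxcl5 where measured. The text uses part of them. Of the last 7 genes Ptpn11 and Cxcl2 passed the filter in CD8 T cells, Cxcr1 did not in tumour cells, and Cxcl5 did not in neutrophils.

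Simulated counts with 200 changed genes were tested in each design. Of 2-fold changes 24% were found in bulk, 47 to 68% in neutrophils, 39 to 63% in CD8 T cells and 57 to 73% in tumour cells, and of 4-fold changes 65% in bulk and at least 86% elsewhere. False calls ran from 2.63 to 9.18%. With genes drawn independently, a planted list was found with 0 of 37 others. Shifts of 3 SD in shares were found in 88% of cases with 5% false calls, unadjusted. Both may overstate how the calls below perform. Bulk replicates differ by a biological coefficient of variation of 30.4%, and the 10 most abundant genes take 3.53 to 4.23% of reads.

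Alternatives were DESeq2 1.42.0, its size factors within edgeR, other filters, the replicate number as a block, pairs of treatments fitted alone, equal cell numbers, limma or untransformed values for shares, another denominator and leaving out each library or mouse. Others were added after the data were seen: parts of the tumour class, tumour cells with at most 2 marker UMIs of other cells, and genes that free RNA could supply (under 5% of the level in another class) left out. Hashtag reads and receptor sequences were not analysed here.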

Results

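Mice with lung tumours received vehicle, SHP099, SX682 or both drugs for 11 days. SHP099 blocks SHP2, the phosphatase encoded by Ptpn11 (chromosome 5, 121130533 to 121191397, 19 exons, mm10), which passes growth factor signals to ERK. SX682 blocks the chemokine receptors CXCR1 and CXCR2, which draw neutrophils into tissue. Bulk RNA came from sorted Epcam+ cells, in 3 SHP099 and 3 vehicle libraries. Single-cell RNA came from nodules of 12 mice, 3 per treatment, in 1 capture per treatment.

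The bulk libraries held 51939301, 52844715 and 52042918 counted reads for vehicle replicates 1 to 3, and 59933609, 58905704 and 73361005 for SHP099. The single-cell matrix held 44986 cells and 32285 genes. Vehicle mice 1 to 3 gave 6399, 3422 and 2632 cells and SHP099 mice gave 3789, 3084 and 2289. SX682 mice gave 3788, 4131 and 2858 cells, and mice on the combination gave 4239, 5421 and 2934. The median number of transcripts (UMIs) per cell ran from 1440 in SHP099 mouse 1 to 4838 in vehicle mouse 3.

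The bulk comparison asked how SHP2 inhibition alters gene expression in Epcam+ cells. The surfactant genes of alveolar type 2 cells, the lung cells that secrete surfactant, were far lower after SHP099. Sftpb, which encodes surfactant protein B (chromosome 6, 72304610 to 72314371), fell from 285 ± 97.7 to 16.7 ± 5.41 CPM (SD, n = 3), a log2 fold change of -4.10 ± 0.35 (SE, adjusted p = 0.0191). Sftpc, which encodes surfactant protein C (chromosome 14, 70520949 to 70524081), fell from 3312 ± 1370.2 to 287 ± 129.5 CPM, or -3.53 ± 0.41 (SE, adjusted p = 0.0415); vehicle tumour cells of the single-cell data held it at 27.8 ± 42.8 CPM (SD, n = 3), or 1.96 CPM where neutrophil transcripts were few. Lamp3, a membrane protein of the organelles that store surfactant, fell from 32.5 ± 6.61 to 3.27 ± 0.913 CPM, or -3.31 ± 0.26 (SE, adjusted p = 0.0146). Ager, a receptor most abundant on alveolar type 1 cells, fell by less, from 50.8 ± 9.31 to 18.7 ± 2.37 CPM, or -1.44 ± 0.17 (SE, adjusted p = 0.0416). Lcn2, a secreted iron-binding protein of inflamed epithelium, fell from 65.9 ± 6.25 to 15.4 ± 1.82 CPM, or -2.10 ± 0.14 (SE, adjusted p = 0.00748). Serinc2, a serine incorporator chosen here after its values were seen, fell from 21.2 ± 0.940 to 2.53 ± 0.234 CPM, or -3.07 ± 0.17 (SE, adjusted p = 0.00315). Values written here as x ± y at an adjusted p are log2 fold changes ± SE. All 3 SHP099 libraries lay below all 3 vehicle libraries for each of these genes. Sftpb lost its call without SHP099 library 1 (-3.98), SHP099 library 2 (-3.96), vehicle library 1 (-3.97) or vehicle library 3 (-3.91). Sftpc lost its call without SHP099 library 1 (-3.33), SHP099 library 2 (-3.37), vehicle library 1 (-3.55), vehicle library 2 (-3.76) or vehicle library 3 (-3.17). Lamp3 lost its call without SHP099 library 1 (-3.19), SHP099 library 2 (-3.21), vehicle library 1 (-3.29) or vehicle library 3 (-3.16). Ager lost its call without SHP099 library 1, 2 or 3 (-1.39, -1.55, -1.36) or vehicle library 1, 2 or 3 (-1.28, -1.55, -1.43). Lcn2 lost its call without SHP099 library 2 (-2.13) or vehicle library 1 (-2.01). Serinc2 lost its call without SHP099 library 2 (-3.06).

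Cxcl5, which encodes a CXCR2 ligand that attracts neutrophils (chromosome 5, 90759360 to 90761624, 4 exons), was the 1 gene that rose, from 94.1 ± 11.1 to 302 ± 63.3 CPM (SD, n = 3), or 1.68 ± 0.17 (SE, adjusted p = 0.0313), higher in 3 of 3 libraries. The neighbouring CXCR2 ligand genes Cxcl1 and Cxcl2 did not pass, at 1.14 ± 0.15 (SE, adjusted p = 0.0569) and 0.42 ± 0.28 (SE, adjusted p = 0.727). Cxcl3 also missed, at 0.80 ± 0.36 at adjusted p = 0.594. Cxcl15, a chemokine of lung epithelium, fell from 58.2 ± 18.5 to 6.26 ± 2.91 CPM, or -3.22 ± 0.38 at adjusted p = 0.0415. Ptpn11 itself stood at 84.5 ± 2.87 v 85.1 ± 4.08 CPM in SHP099 and vehicle libraries (adjusted p = 0.984), and Cxcr1 and Cxcr2 at 2.51 ± 0.85 at adjusted p = 0.421 and 0.34 ± 0.49 at adjusted p = 0.873. The ERK feedback genes Etv5 and Spred2, whose transcripts follow ERK activity in many cells, gave -0.80 ± 0.18 at adjusted p = 0.204 and -0.46 ± 0.13 at adjusted p = 0.276. Among growth factor receptors Egfr gave -0.82 ± 0.16 at adjusted p = 0.147, and Col1a1, a collagen gene of fibroblasts, gave -1.73 ± 0.26 at adjusted p = 0.0814; none of these 4 passed. Cxcl5 lost its call without SHP099 library 1 (1.5), SHP099 library 2 (1.75), vehicle library 1 (1.73), vehicle library 2 (1.77) or vehicle library 3 (1.59). Cxcl15 lost its call without SHP099 library 1 (-3.07), SHP099 library 2 (-3.00), vehicle library 1 (-3.19), vehicle library 2 (-3.41) or vehicle library 3 (-2.97).

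In the edgeR test 23 of 20314 genes passed, 1 higher (Cxcl5) and 22 lower, and 1812 had an unadjusted p under 0.05. All 23 had groups that did not overlap, which 14.9% of tested genes did and chance gives for 10%. Of 13 alveolar type 2 genes 7 fell over all genes and 12 adjusted over the list alone; their median log2 fold change was -3.31 (camera adjusted p = 1.16e-64, adjusted p = 0.0724 with an estimated correlation). The alveolar type 1 list had 1 of 9 genes lower (Ager), 4 adjusted over the list alone, and a median of -0.30 (adjusted p = 0.000149, adjusted p = 0.287 with an estimated correlation). Interferon gamma response genes were higher as a list, with a median of 1.16 over 21 genes and none past the test for single genes, over all genes or adjusted over the list alone (adjusted p = 0.000121, adjusted p = 0.732 with an estimated correlation). The 20 ERK target genes had a median of -0.30, with 0 called over all genes, and 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.00925, adjusted p = 0.633 with an estimated correlation). Of 6 CXCR2 ligand genes 1 rose and 1 fell over all genes, and 2 rose and 1 fell adjusted over the list alone. Their median was 0.61 and their mean -0.10, and camera called the list higher (adjusted p = 0.00498, adjusted p = 0.287 with an estimated correlation).

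The count was 3 without SHP099 library 1, 0 without SHP099 library 2 (1471 genes at an unadjusted p under 0.05), 16 without SHP099 library 3, 2 without vehicle library 1, 9 without vehicle library 2 and 4 without vehicle library 3. DESeq2 called 569 genes on all 6 libraries, 69 higher and 500 lower. With the genes that mark the alveolar and airway cells of the single-cell data left out, 2 genes passed, Lcn2 and Serinc2, and Cxcl5 gave 1.67 without a call. With 3 libraries against 3 an exact permutation test cannot give a p below 0.1.

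**Figure D1:**
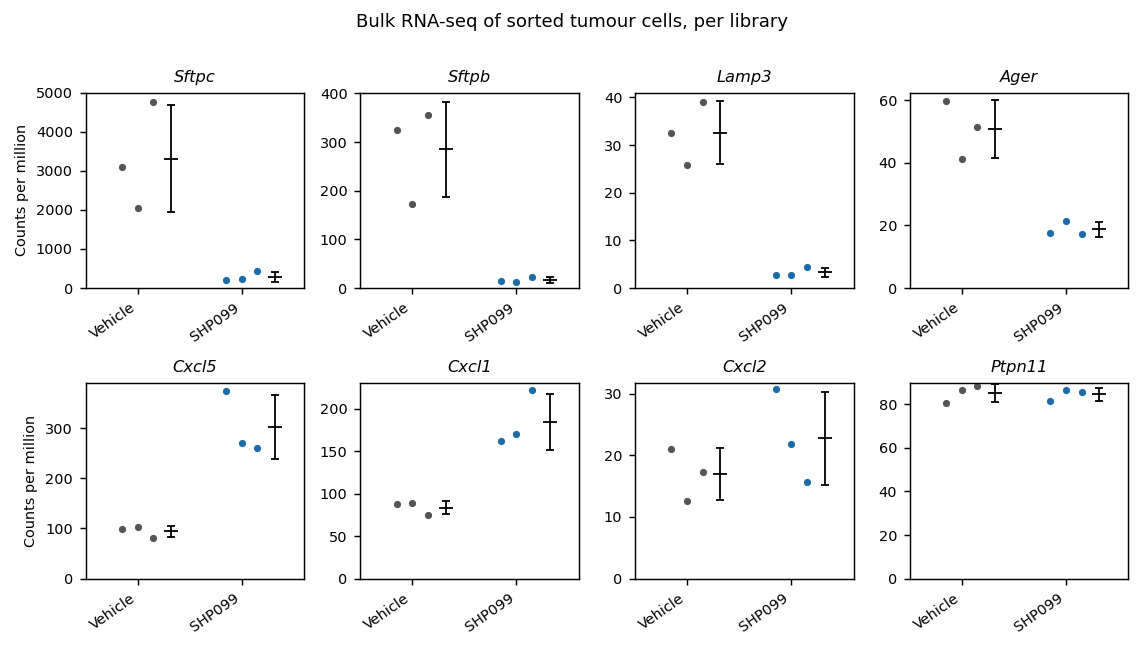
CPM of Sftpc, Sftpb, Lamp3, Ager, Cxcl5, Cxcl1, Cxcl2 and Ptpn11 in each bulk library of Epcam+ cells, with points for libraries and the dash and bar for the mean ± SD of n = 3. Sftpc averages 3312 CPM in vehicle and 287 CPM in SHP099 libraries, Cxcl5 94.1 and 302 CPM, and Ptpn11 85.1 and 84.5 CPM.

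The single-cell comparisons asked how each drug and the combination alter the tumour and its surroundings. Each treatment was captured in 1 pool, so capture and treatment cannot be told apart in any of them. The labels give no information on doublets, and no doublet caller was applied here. Counts are uncertain for genes whose exons overlap those of another gene (Krt8, Aldoa, Cp, Vcam1, Pim1, Nsd2, Bnip3, Cd74, Pkm, Fdps, Rnaset2b, Cx3cr1, Erh, Tnfaip2, Gbp2) and for H2-Q7 and Hspa1a, which have near-identical neighbours. For each gene said to rise or fall, all 3 mice of the first group lay on that side of the other group's mean, except where another number is given.

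Tumour cells made up 18.3 ± 3.44% of cells in vehicle mice and 2.42 ± 0.337% after SHP099 (SD, n = 3 mice), 6.59 ± 3.23% after SX682 and 7.4 ± 0.929% after the combination. Macrophages, which clear debris and shape immunity in tumours, made up 21.2 ± 5.71%, 6.21 ± 0.953%, 15.8 ± 2.67% and 8.30 ± 1.76% in the same order. Dendritic cells, which present antigen to T cells, made up 8.05 ± 2.3%, 3.32 ± 0.95%, 8.85 ± 2.58% and 2.99 ± 0.412%. These 3 of 16 classes differed between the 4 treatments in an exact permutation test on 12 mice (adjusted p = 0.00519, 0.00519 and 0.0319). Neutrophils made up 13 ± 3.11%, 30.7 ± 4.69%, 15 ± 7.64% and 26.5 ± 4.06% and T cells 9.36 ± 0.848%, 23.3 ± 2.80%, 18.1 ± 11.9% and 18.2 ± 3.18%. They did not pass that test (exact adjusted p = 0.0691 and 0.115), nor did fibroblasts (0.0564), alveolar macrophages (0.0691), B cells (0.181), NK cells (0.193), alveolar and airway epithelial cells (0.462), endothelial cells (0.462), plasma cells (0.576) or monocytes (0.95). The unnamed clusters 14, 22 and 27 gave 0.0691, 0.165 and 0.0691.

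In edgeR tests on cell counts, SHP099 lowered the share of tumour cells (log2 fold change -2.92 ± 0.38, adjusted p = 4.78e-05), macrophages (-1.77 ± 0.32, adjusted p = 0.000753), fibroblasts (-2.83 ± 0.54, adjusted p = 0.000877) and dendritic cells (-1.28 ± 0.36, adjusted p = 0.0128). The same test gave higher shares of T cells (1.31 ± 0.40, adjusted p = 0.0181) and neutrophils (1.24 ± 0.41, adjusted p = 0.0241) after SHP099. Cluster 22, which has no name, was lower (-2.3, adjusted p = 0.038). SX682 alone lowered tumour cells (-1.47 ± 0.36, adjusted p = 0.0182). The combination lowered tumour cells (-1.31 ± 0.35, adjusted p = 0.0141), macrophages (-1.35 ± 0.32, adjusted p = 0.0116) and dendritic cells (-1.42 ± 0.36, adjusted p = 0.0116), and gave 1.02 ± 0.40 for neutrophils (adjusted p = 0.0786) and 0.96 ± 0.40 for T cells (adjusted p = 0.0799). Against SHP099 alone, the combination had more tumour cells (1.61 ± 0.36, adjusted p = 0.0102), fibroblasts (2.06 ± 0.55, adjusted p = 0.0187) and alveolar macrophages (1.12 ± 0.33, adjusted p = 0.0249).

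Shares add up to 100%, so a lower share of tumour cells raises the others. With tumour and epithelial cells left out of the total, macrophages, dendritic cells, fibroblasts and alveolar macrophages differed between treatments (exact adjusted p = 0.00182, 0.0421, 0.0421 and 0.0475), and neutrophils after SHP099 lost their edgeR call (log2 fold change 0.98). The number of classes past the permutation test was 5, 8 and 7 without SX682 mouse 1, 2 and 3. After SHP099 the neutrophil call was lost without vehicle mouse 2 (1.24), vehicle mouse 3 (1.07), SHP099 mouse 2 (1.1) or SHP099 mouse 3 (1.30). The T cell call was lost without vehicle mouse 3 (1.26) or SHP099 mouse 3 (1.22), and the dendritic cell call without vehicle mouse 3 (-1.12) or SHP099 mouse 1 (-1.08). The tumour cell call of SX682 was lost without vehicle mouse 3 (-1.31) or SX682 mouse 2 (-1.28). For the combination, vehicle mouse 3, combination mouse 1 and combination mouse 2 each decided 3 calls. Without them in that order, tumour cells gave -1.15, -1.21 and -1.34, macrophages -1.11, -1.19 and -1.40, and dendritic cells -1.26, -1.54 and -1.37. Without SX682 mouse 3 the combination gained calls for neutrophils (1.02), T cells (0.96), alveolar macrophages (0.85) and fibroblasts (-0.78). Against SHP099 the alveolar macrophage call was lost without SHP099 mouse 2 (1.07), SHP099 mouse 3 (0.98), combination mouse 1 (1.04) or combination mouse 2 (1.04). The fibroblast call there was lost without SHP099 mouse 2 (2.01), SHP099 mouse 3 (2.06) or combination mouse 1 (1.89), and the tumour cell call without SHP099 mouse 3 (1.63).

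**Figure D2:**
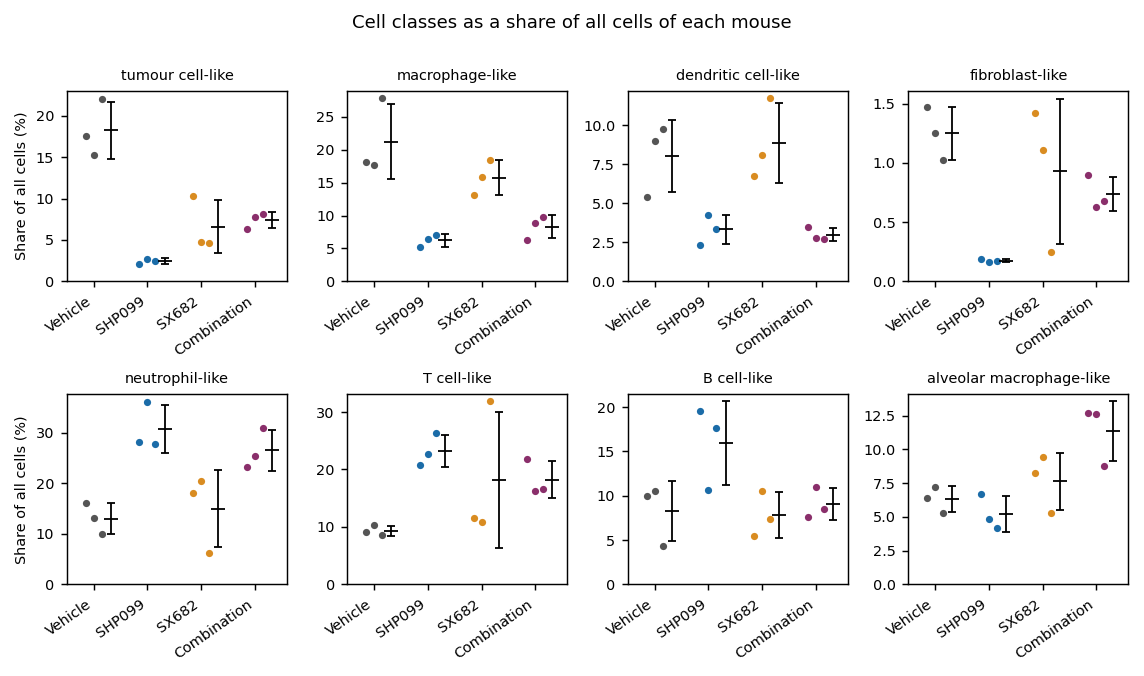
Share of all cells, in percent, that each of 8 cell classes takes in each mouse, with points for mice and the dash and bar for the mean ± SD of n = 3. Tumour cells average 18.3% in vehicle and 2.42% in SHP099 mice, and neutrophils 13% and 30.7%.

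Neutrophils of the deposited neutrophil table fall into 6 clusters. Cluster N3, led by the chemokine genes Ccl4 and Ccl3, took 8.74 ± 1.12% of neutrophils in vehicle, 23.5 ± 2.26% in SHP099, 18.4 ± 9.08% in SX682 and 30.1 ± 5.63% in combination mice (SD, n = 3, exact permutation adjusted p = 0.0152). Cluster N6, led by Retnlg, a gene of young circulating neutrophils, took 30.1 ± 12%, 13.6 ± 2.88%, 21.6 ± 10.9% and 8.31 ± 2.76% (exact adjusted p = 0.0362). Cluster N2, led by Il23a and Cxcl1, took 21.2 ± 1.97%, 13.1 ± 1.87%, 20.7 ± 1.51% and 16.1 ± 1.33% (exact adjusted p = 0.0074). Cluster N5, led by Cxcl3 and the interferon gene Isg15 among others, took 4.84 ± 1.56%, 10.9 ± 1.96%, 6.04 ± 2.94% and 11.7 ± 2.65% (exact adjusted p = 0.0671). Clusters N1 and N4 gave exact adjusted p = 0.618 and 0.647.

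Against vehicle, edgeR on cell counts gave N3 log2 fold changes of 1.44 ± 0.32 in SHP099 (adjusted p = 0.00563), 1.1 ± 0.33 in SX682 (adjusted p = 0.0376) and 1.80 ± 0.32 in combination mice (adjusted p = 0.00116). N6 fell after SHP099 (-1.16 ± 0.40, adjusted p = 0.023) and the combination (-1.87 ± 0.41, adjusted p = 0.00265), and N2 fell after SHP099 (-0.69 ± 0.17, adjusted p = 0.00563). N5 gave 1.18 ± 0.37 after SHP099 (adjusted p = 0.0172) and 1.29 ± 0.37 after the combination (adjusted p = 0.0102). The genes that define N3 (Ccl4, Ccl3, Cstb) and N6 (Retnlg, Wfdc17) also differ between treatments over all neutrophils, so share and level are 1 observation. The number of neutrophil clusters past the permutation test was 1 without vehicle mouse 1 or without vehicle mouse 2. The N6 call after SHP099 was lost without vehicle mouse 1 (-0.78), SHP099 mouse 2 (-0.99) or SHP099 mouse 3 (-1.19). The N3 call after SX682 was lost without vehicle mouse 1 (0.99), vehicle mouse 2 (1.14), vehicle mouse 3 (1.17) or SX682 mouse 2 (0.59), and also (at 1.1) without SHP099 mouse 1, 2 or 3 or combination mouse 1.

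In neutrophils, summed per mouse, SHP099 raised Csf1, a macrophage growth factor gene, from 108 ± 9.98 to 239.9 ± 7.76 CPM (SD, n = 3), a log2 fold change of 1.17 ± 0.16 (SE, adjusted p = 8.42e-05). Vegfa, which drives blood vessel growth, rose from 265 ± 86.6 to 552 ± 74.4 CPM, or 1.12 ± 0.18 (SE, adjusted p = 0.0004). Cxcr4, a receptor that marks aged neutrophils, rose (0.99 ± 0.13 at adjusted p = 8.06e-05), and Siglecf, a lectin found on tumour-promoting neutrophils (chromosome 7, 43351341 to 43359531), rose (0.67 ± 0.17 at adjusted p = 0.0124). Retnlg (chromosome 16, 48872621 to 48874496) fell from 6082 ± 1300.4 to 1924 ± 574 CPM, or -1.66 ± 0.26 at adjusted p = 0.000254. The granule and early maturation genes Chil3 and Mmp8 fell as well, with -2.33 ± 0.40 at adjusted p = 0.00069 and -2.02 ± 0.41 at adjusted p = 0.00249. The CXCR2 ligand Cxcl1 fell from 118 ± 12.6 to 31.2 ± 8.33 CPM, or -1.93 ± 0.28 at adjusted p = 0.000124. Cxcl2 and Cxcl3 fell by less, with -0.42 ± 0.13 at adjusted p = 0.0347 and -0.76 ± 0.18 at adjusted p = 0.00914. Cxcr2, the receptor that SX682 blocks, gave 0.04 ± 0.14 at adjusted p = 0.902, with 235 ± 20.8 v 226 ± 38.9 CPM in SHP099 and vehicle mice, and Ptpn11 gave 0.07 ± 0.23 at adjusted p = 0.888. Cxcr1 had only 10.3 and 10.5 CPM in the same groups (adjusted p = 0.627). Siglecf lost its call without vehicle mouse 1 (0.46). Cxcl2 lost its call without vehicle mouse 1 (-0.34), vehicle mouse 3 (-0.44), SHP099 mouse 2 (-0.36) or SHP099 mouse 3 (-0.40). Cxcl3 lost its call without vehicle mouse 1 (-0.62) or vehicle mouse 3 (-0.62).

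Of 7477 genes tested in neutrophils 446 were higher and 531 lower after SHP099, and 2017 had an unadjusted p under 0.05. Of the 977, 922 had groups that did not overlap, as did 29.5% of tested genes, where chance gives 10%. Keratin genes of tumour cells were lower: Krt8 fell from 188 ± 34.4 to 26 ± 6.87 CPM, or -2.90 ± 0.22 at adjusted p = 1.87e-07, and the list of 6 tumour epithelial genes had 3 lower, 4 adjusted over the list alone, and a median of -1.47 (camera adjusted p = 2.35e-13, adjusted p = 0.00161 with an estimated correlation). Macrophage genes were lower too, with Apoe at -2.13 ± 0.25 at adjusted p = 1.34e-05; 4 of 9 fell and 1 rose, against 7 and 1 adjusted over the list alone, with a median of -1.67 (adjusted p = 0.000252, adjusted p = 0.0387 with an estimated correlation). Neutrophils do not normally make keratins or much Apoe, so these values include transcripts of other cells. The 18 genes of Siglecf-high neutrophils had 7 higher, 8 adjusted over the list alone, with a median of 0.28 (adjusted p = 0.0022, adjusted p = 0.152 with an estimated correlation). The 3 measured CXCR2 ligand genes all fell, also adjusted over the list alone, with a median of -0.76 (adjusted p = 0.00074, adjusted p = 0.152 with an estimated correlation). The count was 548 without vehicle mouse 1.

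SX682 changed fewer neutrophil genes. Wfdc17, a secreted antiprotease gene of immature neutrophils, fell from 2144 ± 1183 to 555 ± 54.0 CPM (SD, n = 3), a log2 fold change of -1.98 ± 0.32 (SE, adjusted p = 0.00413). S100a10, a calcium-binding protein gene, fell from 219 ± 27 to 92.1 ± 11.8 CPM, or -1.21 ± 0.16 (SE, adjusted p = 0.000475). The related S100a6 and the protease inhibitor gene Stfa2l1 fell too, at -1.19 ± 0.21 at adjusted p = 0.00678 and -1.59 ± 0.26 at adjusted p = 0.00463. Cxcl1 fell from 118 ± 12.6 to 31.1 ± 24.1 CPM, or -1.58 ± 0.28 at adjusted p = 0.00766, whereas Cxcl2 and Cxcl3 did not pass (-0.14 ± 0.13 at adjusted p = 0.813 and -0.61 ± 0.19 at adjusted p = 0.195). Retnlg also missed the threshold (-1.09 ± 0.25 at adjusted p = 0.0602). The genes of the drug's targets, Cxcr1 and Cxcr2, gave -1.1 ± 0.50 at adjusted p = 0.478 and -0.17 ± 0.15 at adjusted p = 0.801, and Ptpn11 gave 0.29 ± 0.25 at adjusted p = 0.79. Scgb1a1, the secretoglobin of airway club cells, rose from 7.26 ± 5.17 to 181 ± 50.4 CPM (4.61 ± 0.37 at adjusted p = 5.78e-07), and Krt8 fell (-1.36 ± 0.20 at adjusted p = 0.00202); both are transcripts that other cells make. S100a6 lost its call without vehicle mouse 1 (-0.98) or SX682 mouse 2 (-1.16). Stfa2l1 lost its call without SX682 mouse 2 (-1.25). Cxcl1 lost its call without vehicle mouse 1 (-1.63). Cxcl3 gained a call without vehicle mouse 2 (-0.85). Retnlg gained a call without SX682 mouse 1 (-1.5).

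In all, 6 neutrophil genes were higher and 32 lower after SX682, with 724 at an unadjusted p under 0.05. All 38 had groups that did not overlap, against 13.2% of tested genes and 10% by chance. Of 16 S100 and suppressor-type genes 4 fell, against 7 lower and 1 higher adjusted over the list alone, with a median of -0.17 (camera adjusted p = 3.57e-07, adjusted p = 0.219 with an estimated correlation). Of the 3 CXCR2 ligand genes 1 fell (Cxcl1), 2 adjusted over the list alone, with a median of -0.61 (adjusted p = 4e-05, adjusted p = 0.091 with an estimated correlation). The 6 tumour epithelial genes had 3 lower, also adjusted over the list alone, and a median of -0.72 (adjusted p = 6.77e-08, adjusted p = 0.00995 with an estimated correlation). The count was 12 without vehicle mouse 1 and 14 without SX682 mouse 2.

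The combination raised the chemokine genes Ccl4, from 1985 ± 316 to 4019 ± 1159.5 CPM (SD, n = 3), a log2 fold change of 1.02 ± 0.18 (SE, adjusted p = 0.00162), and Ccl3, at 0.87 ± 0.17 (SE, adjusted p = 0.00328). Csf1 rose from 108 ± 9.98 to 268 ± 19.7 CPM, or 1.33 ± 0.16 at adjusted p = 8.46e-05, and Cxcr4 rose (1.12 ± 0.13 at adjusted p = 8.46e-05). Retnlg fell from 6082 ± 1300.4 to 1129 ± 127 CPM, or -2.43 ± 0.26 at adjusted p = 3.53e-05. The granule genes Chil3, Mmp8 and Ngp fell, (-2.62 ± 0.40 at adjusted p = 0.000623, -2.35 ± 0.42 at adjusted p = 0.00216 and -3.29 ± 0.76 at adjusted p = 0.0116). S100a9, an alarmin that makes up much of the neutrophil cytosol, fell (-0.85 ± 0.16 at adjusted p = 0.0033). H2-K1 and B2m, which encode parts of MHC class I, rose (0.92 ± 0.14 at adjusted p = 0.000567 and 0.65 ± 0.10 at adjusted p = 0.000722). Cxcl1 fell (-1.24 ± 0.26 at adjusted p = 0.00636) and so did Cxcl3 (-0.62 ± 0.18 at adjusted p = 0.0472); Cxcl2 gave -0.19 ± 0.13 at adjusted p = 0.445. Cxcr1, Cxcr2 and Ptpn11 gave 0.73 ± 0.37 at adjusted p = 0.28, -0.20 ± 0.14 at adjusted p = 0.469 and 0.03 ± 0.24 at adjusted p = 0.987. Scgb1a1 rose (3.94 ± 0.38 at adjusted p = 1.29e-05), as did Ccl5, a T cell and NK cell chemokine gene (3.05 ± 0.46 at adjusted p = 0.000567). Ngp lost its call without combination mouse 1 (-3.19) or combination mouse 3 (-2.85). Cxcl3 lost its call without vehicle mouse 1 (-0.49), vehicle mouse 3 (-0.48), combination mouse 1 (-0.57) or combination mouse 3 (-0.49).

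Against vehicle the combination had 242 higher and 240 lower neutrophil genes, with 1523 at an unadjusted p under 0.05. Of the 482, 463 had groups that did not overlap, against 24.4% of tested genes and 10% by chance. Of 14 secondary granule genes 6 fell, 8 adjusted over the list alone, with a median of -1.14 (camera adjusted p = 5.62e-08, adjusted p = 0.129 with an estimated correlation). Of 18 Siglecf-high neutrophil genes 8 rose, 10 adjusted over the list alone, with a median of 0.40 (adjusted p = 1.03e-05, adjusted p = 0.0634 with an estimated correlation). Of 13 MHC class I genes 4 rose, 5 adjusted over the list alone, with a median of 0.21 (adjusted p = 0.000456, adjusted p = 0.219 with an estimated correlation). Of 8 cytotoxic genes, which lymphocytes make, 5 rose, also adjusted over the list alone, with a median of 0.95 (adjusted p = 1.19e-07, adjusted p = 0.0577 with an estimated correlation). The 6 tumour epithelial genes had 3 lower, 4 adjusted over the list alone, and a median of -0.71 (adjusted p = 2.41e-05, adjusted p = 0.0488 with an estimated correlation). The count was 216 without vehicle mouse 1, 281 without combination mouse 1 and 279 without combination mouse 2.

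Setting the combination against SHP099 alone asked what SX682 adds. The genes with the largest differences in neutrophils are made by other cells. Scgb1a1 rose from 2.57 ± 1.68 to 117 ± 34.9 CPM (SD, n = 3), a log2 fold change of 5.44 ± 0.37 (SE, adjusted p = 3.88e-08). Krt8, Krt19 and Krt18 rose (1.95 ± 0.21 at adjusted p = 3.37e-05, 2.08 ± 0.29 at adjusted p = 0.000359 and 1.1 ± 0.20 at adjusted p = 0.00756). Osm, a cytokine gene of activated neutrophils, fell from 595 ± 81.5 to 396 ± 58.5 CPM, or -0.58 ± 0.14 at adjusted p = 0.0482, and Sirpa, an inhibitory receptor gene, fell (-0.51 ± 0.12 at adjusted p = 0.0349). Cxcl1, Cxcl2 and Cxcl3 gave 0.69 ± 0.28 at adjusted p = 0.332, 0.23 ± 0.13 at adjusted p = 0.533 and 0.14 ± 0.18 at adjusted p = 0.844. Cxcr1 and Cxcr2 gave 1.1 ± 0.33 at adjusted p = 0.142 and -0.24 ± 0.14 at adjusted p = 0.549, Retnlg -0.77 ± 0.25 at adjusted p = 0.206 and Ptpn11 -0.04 ± 0.20 at adjusted p = 0.973; none of these 7 passed. In all 76 genes were higher and 12 lower, with 847 at an unadjusted p under 0.05. All 88 had groups that did not overlap, against 18.4% of tested genes and 10% by chance. The 6 tumour epithelial genes had 3 higher, also adjusted over the list alone, and a median of 0.74 (camera adjusted p = 1.26e-08, adjusted p = 0.0074 with an estimated correlation). The count was 42, 47 and 56 without SHP099 mouse 1, 2 and 3, and 54 and 51 without combination mouse 1 and 3. It was 11 (9 higher) without genes that free RNA could supply and 3 with equal cell numbers per mouse. Krt18 lost its call without SHP099 mouse 1 (1.06) or combination mouse 2 (0.99). Osm lost its call without SHP099 mouse 1 (-0.51), SHP099 mouse 3 (-0.55), combination mouse 1 (-0.50) or combination mouse 3 (-0.56). Sirpa lost its call without SHP099 mouse 1 (-0.46), SHP099 mouse 3 (-0.48), combination mouse 1 (-0.53), combination mouse 2 (-0.53) or combination mouse 3 (-0.49).

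T cells of the deposited T cell table fall into 9 clusters. Cluster T5, cycling CD8-like cells, took 3.16 ± 0.717% of T cells in vehicle, 3.30 ± 0.901% in SHP099, 4.58 ± 1.27% in SX682 and 8.20 ± 1.37% in combination mice (SD, n = 3, exact permutation adjusted p = 0.0497). Cluster T2, CD8-like cells with the effector gene Klrg1, took 4.13 ± 1.84%, 2.92 ± 1.04%, 2.89 ± 1.19% and 11.3 ± 6.05% (exact adjusted p = 0.0921). Regulatory-like cluster T6, led by Foxp3, took 10.6%, 5.36%, 8.66% and 6.43% (exact adjusted p = 0.0921), and exhausted CD8-like cluster T9, with Lag3 among its leading genes, took 6.90%, 4.05%, 8.70% and 2.77% (exact adjusted p = 0.643). The naive CD8-like T1, the CD8-like T3, the naive-like T4, the unnamed T7 and T8, led by genes of the gamma delta receptor (Trdv4, Tcrg-C1), gave exact adjusted p = 0.592, 0.793, 0.703, 0.394 and 0.793. In edgeR tests on cell counts the combination raised T5 against vehicle (log2 fold change 1.42 ± 0.35, adjusted p = 0.00861) and against SHP099 (1.32 ± 0.32, adjusted p = 0.00395), and against SX682 T5 did not pass (0.87 ± 0.32, adjusted p = 0.0677). The same tests gave T2 a higher share than in vehicle (1.45 ± 0.47, adjusted p = 0.0335), SHP099 (1.94 ± 0.45, adjusted p = 0.00395) and SX682 mice (2.01 ± 0.47, adjusted p = 0.00581). No T cell cluster passed the permutation test (0 of 9) without vehicle mouse 1, 2 or 3, SHP099 mouse 1 or 3, SX682 mouse 1 or 2, or combination mouse 1, 2 or 3. The T2 call against vehicle was lost without vehicle mouse 1 (1.25), vehicle mouse 3 (1.31), combination mouse 1 (0.93) or combination mouse 3 (1.51), and the T5 call without vehicle mouse 1 (1.27). T6 after SHP099 (-0.96 ± 0.33, adjusted p = 0.102) gained a call without SHP099 mouse 2 (-1.21). T2 and T5 are part of the CD8 T cells tested for genes, so their shares and the levels of their effector and cell cycle genes are 1 observation.

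**Figure D3:**
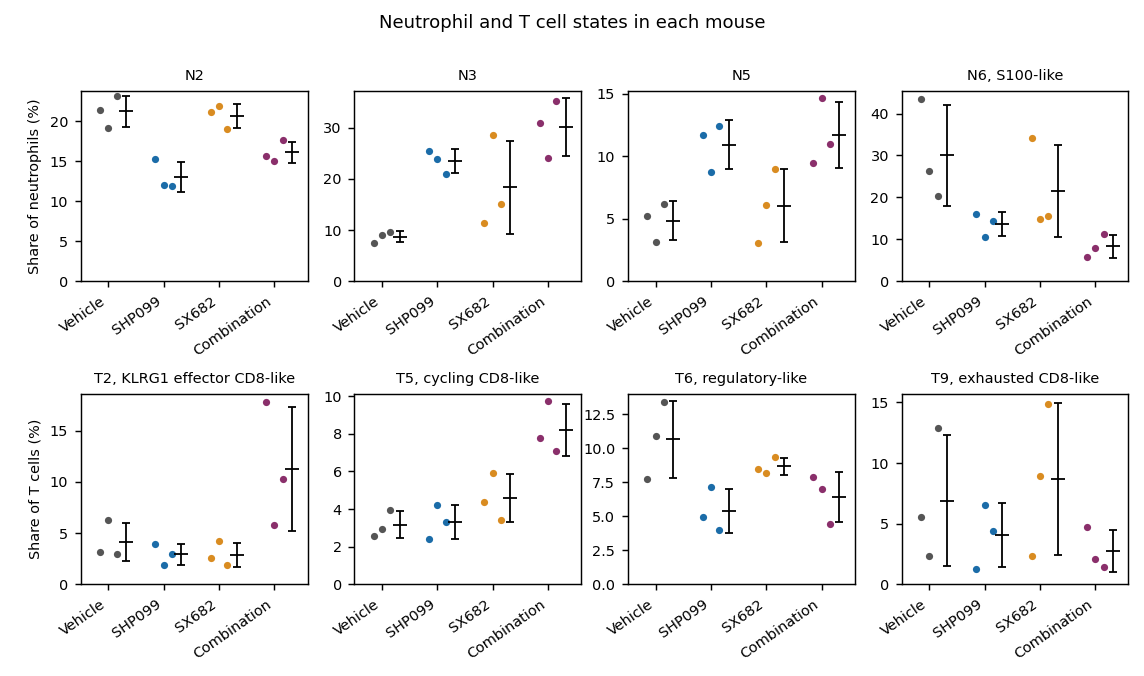
Percent of neutrophils in clusters N2, N3, N5 and N6 and percent of T cells in clusters T2, T5, T6 and T9 for each mouse, with points for mice and the dash and bar for the mean ± SD of n = 3. N3 averages 8.74% in vehicle and 30.1% in combination mice, and T5 averages 3.16% and 8.20%.

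In CD8 T cells after SHP099 Aldoa, which encodes an aldolase of glycolysis, fell from 328 ± 40.3 to 160.2 ± 19.2 CPM (SD, n = 3), a log2 fold change of -1.03 ± 0.16 (SE, adjusted p = 0.000142). Pkm and Pgk1, which encode 2 other enzymes of glycolysis, fell (-0.72 ± 0.18 at adjusted p = 0.0127 and -0.49 ± 0.15 at adjusted p = 0.0433). Cd3g, a subunit of the T cell receptor complex, fell from 957 ± 181 to 577 ± 38.7 CPM, or -0.72 ± 0.13 (SE, adjusted p = 0.00101). Klrd1, a receptor gene of cytotoxic cells, fell (-0.90 ± 0.20 at adjusted p = 0.00519), as did Tigit, an inhibitory receptor gene of exhausted cells (-1.64 ± 0.35 at adjusted p = 0.00495). Pim1, a kinase gene that follows cytokine signals, rose from 83.5 ± 21.5 to 210.1 ± 25.5 CPM, or 1.25 ± 0.19 at adjusted p = 0.000134, and Tnfaip3, which restrains NF-kB, rose (1.13 ± 0.21 at adjusted p = 0.00138). Gzmb, the granzyme gene of killer cells (chromosome 14, 56258838 to 56262260), gave -0.30 ± 0.26 at adjusted p = 0.545. Ptpn11 and Cxcl2 gave -0.39 ± 0.31 at adjusted p = 0.49 and -1.12 ± 0.48 at adjusted p = 0.174. Apoe and Krt18, which other cells make, fell (-2.24 ± 0.25 at adjusted p = 4.83e-06 and -2.58 ± 0.57 at adjusted p = 0.00622). Pkm lost its call without vehicle mouse 3 (-0.54), SHP099 mouse 1 (-0.65) or SHP099 mouse 3 (-0.65). Pgk1 lost its call without vehicle mouse 1, 2 or 3 (-0.58, -0.47, -0.41) or SHP099 mouse 1, 2 or 3 (-0.48, -0.50, -0.48). Klrd1 lost its call without vehicle mouse 3 (-0.62). Tigit lost its call without vehicle mouse 3 (-1.19). Cxcl2 gained a call without SHP099 mouse 3 (-2.25).

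Of 6764 genes tested in CD8 T cells 177 were higher and 261 lower after SHP099, with 1501 at an unadjusted p under 0.05. Of the 438, 425 had groups that did not overlap, against 26% of tested genes and 10% by chance. Of 10 glycolysis genes 3 fell, 5 adjusted over the list alone, with a median of -0.46 (camera adjusted p = 0.0254, adjusted p = 0.253 with an estimated correlation). Of 15 cytotoxic genes 2 fell, 4 adjusted over the list alone, with a median of -0.45 (adjusted p = 0.0254, adjusted p = 0.585 with an estimated correlation). Of 14 exhaustion genes 2 fell, also adjusted over the list alone, but the list was not called (median -0.19, adjusted p = 0.534). The count was 250, 278 and 288 without vehicle mouse 1, 2 and 3, and 282 and 281 without SHP099 mouse 1 and 3.

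After SX682, CD8 T cells had 6 higher and 11 lower genes, with 507 at an unadjusted p under 0.05 and groups that did not overlap for all 17 (12.4% of tested genes, 10% by chance). DESeq2 divided its 33 calls into 7 higher and 26 lower. Scgb1a1, the airway secretoglobin, rose from 2.65 ± 4.59 to 86.8 ± 14 CPM (SD, n = 3), a log2 fold change of 4.38 ± 0.50 (SE, adjusted p = 2.36e-05). Lars2, which encodes a mitochondrial tRNA ligase, rose (0.85 ± 0.15 at adjusted p = 0.00836), and Cirbp, a cold-inducible RNA-binding protein gene, fell (-0.98 ± 0.20 at adjusted p = 0.0312). Ptpn11 and Cxcl2 gave -0.43 ± 0.31 at adjusted p = 0.838 and -1.23 ± 0.49 at adjusted p = 0.588. None of the 25 cell cycle genes passed, also adjusted over the list alone, but their median was 0.51 and camera called the list (adjusted p = 1.29e-08, adjusted p = 0.47 with an estimated correlation). The count was 1 (higher) and 9 without vehicle mouse 1 and 2, and 4 and 9 (3 and 6 higher) without SX682 mouse 2 and 3. Lars2 lost its call without vehicle mouse 1 (0.77) or vehicle mouse 2 (0.79). Cirbp lost its call without vehicle mouse 1 (-0.84), vehicle mouse 2 (-1.06), vehicle mouse 3 (-1.01), SX682 mouse 2 (-0.98) or SX682 mouse 3 (-0.86).

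The combination raised the DNA replication genes Top2a and Pcna and the granule protease gene Gzmb in CD8 T cells. Top2a, a topoisomerase gene of dividing cells, rose from 119 ± 37.4 to 261 ± 74.4 CPM (SD, n = 3), a log2 fold change of 1.19 ± 0.25 (SE, adjusted p = 0.00643). Pcna, the clamp of the replication fork, rose by 0.89 ± 0.19 (SE, adjusted p = 0.00886). Gzmb rose from 96.9 ± 60.5 to 237 ± 17.2 CPM, or 1.15 ± 0.24 (SE, adjusted p = 0.00643). Ccr7 and Tcf7, a homing receptor and a transcription factor of naive and memory T cells, fell (-1.35 ± 0.28 at adjusted p = 0.00578 and -0.61 ± 0.17 at adjusted p = 0.0403). Klrg1 and Cx3cr1, which mark effector cells, gave 2.11 ± 0.76 at adjusted p = 0.143 and 1.39 ± 0.41 at adjusted p = 0.0559 and did not pass. Fos, an immediate early gene, fell (-1.19 ± 0.25 at adjusted p = 0.00643). Ptpn11 and Cxcl2 gave -0.17 ± 0.30 at adjusted p = 0.828 and 0.50 ± 0.42 at adjusted p = 0.607. Ebf1 and Scgb1a1, which B cells and airway cells make, rose too (4.00 ± 0.63 at adjusted p = 0.000642 and 4.24 ± 0.51 at adjusted p = 3.06e-05). Top2a lost its call without vehicle mouse 1 (0.93). Pcna lost its call without vehicle mouse 1 (0.91) or combination mouse 2 (0.70). Ccr7 lost its call without vehicle mouse 1 (-1.25). Tcf7 lost its call without vehicle mouse 1 (-0.36), combination mouse 1 (-0.57), combination mouse 2 (-0.63) or combination mouse 3 (-0.60). Klrg1 gained a call without vehicle mouse 2 (5.11). Cx3cr1 gained a call without combination mouse 2 (1.75).

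In all 110 CD8 T cell genes were higher and 107 lower after the combination than after vehicle, with 1087 at an unadjusted p under 0.05. Of the 217, 209 had groups that did not overlap, against 20.2% of tested genes and 10% by chance. Of 25 cell cycle genes 5 rose, 13 adjusted over the list alone, with a median of 0.75 (camera adjusted p = 6.11e-10, adjusted p = 0.309 with an estimated correlation). Of 13 genes of the Klrg1 effector list 0 passed over all genes and 5 rose adjusted over the list alone, with a median of 0.24 (adjusted p = 0.0371, adjusted p = 0.542 with an estimated correlation). Of 12 naive T cell genes 2 fell, 4 adjusted over the list alone, with a median of -0.39 (adjusted p = 0.012, adjusted p = 0.578 with an estimated correlation). Of 15 cytotoxic genes 1 rose and 1 fell, against 1 and 2 adjusted over the list alone, and the list was not called (median 0.37, adjusted p = 0.172). The count was 70 and 143 without vehicle mouse 1 and 2, and 124 and 121 without combination mouse 1 and 2.

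Against SHP099 alone, the combination raised Gzmb in CD8 T cells from 86.3 ± 13.5 to 237 ± 17.2 CPM (SD, n = 3), a log2 fold change of 1.44 ± 0.22 (SE, adjusted p = 0.000487). The chemokine genes Ccl3 and Ccl4, which effector T cells release, rose (1.75 ± 0.40 at adjusted p = 0.0279 and 1.66 ± 0.40 at adjusted p = 0.0398), and Ccl5 gave 0.74 ± 0.20 at adjusted p = 0.0636. Ccl3 and Ccl4 also lead neutrophil cluster N3, and whether carried neutrophil transcripts add to their values was not tested. Tcf7 fell (-0.77 ± 0.16 at adjusted p = 0.0112), and Ccr7 gave -0.79 ± 0.26 at adjusted p = 0.145. Ptpn11 and Cxcl2 gave 0.21 ± 0.27 at adjusted p = 0.775 and 1.62 ± 0.42 at adjusted p = 0.0554. The MHC class II gene H2-Ab1 and the antibody chain gene Jchain, which B cells and plasma cells make, rose (2.10 ± 0.28 at adjusted p = 0.000144 and 7.73 ± 1.12 at adjusted p = 0.000281). In all 46 genes were higher and 22 lower, with 972 at an unadjusted p under 0.05. Of the 68, 65 had groups that did not overlap, against 19.2% of tested genes and 10% by chance. Of 15 cytotoxic genes 3 rose, 7 adjusted over the list alone, with a median of 0.48 (camera adjusted p = 1e-07, adjusted p = 0.0544 with an estimated correlation). Of 12 naive T cell genes 1 fell, 5 adjusted over the list alone, with a median of -0.45 (adjusted p = 2.29e-05, adjusted p = 0.288 with an estimated correlation). The 14 exhaustion genes had 0 called over all genes and 1 lower adjusted over the list alone, a median of -0.14, a mean of -0.00 and a camera direction of higher (adjusted p = 0.767). The neutrophil S100 list of 11 genes (1 higher, 7 adjusted over the list alone, median 0.56) and that of 3 plasma cell genes (2 higher, also adjusted over the list alone, median 1.75) were called as well. Their camera adjusted p were 2.13e-09 and 5.71e-05, with adjusted p = 0.0358 for both with an estimated correlation. The count was 27 without SHP099 mouse 1 and 31 without combination mouse 2, and 58 (26 higher, 32 lower) with equal cell numbers per mouse. Ccl3 lost its call without SHP099 mouse 1 (1.62), SHP099 mouse 2 (1.71), SHP099 mouse 3 (1.95) or combination mouse 3 (1.09). Ccl4 lost its call without SHP099 mouse 1 (1.26), SHP099 mouse 2 (1.76) or combination mouse 3 (0.89). Ccl5 gained a call without SHP099 mouse 1 (0.98) or combination mouse 2 (0.98). Tcf7 lost its call without SHP099 mouse 1 (-0.59). Ccr7 gained a call without combination mouse 3 (-1.1). Cxcl2 gained a call without SHP099 mouse 3 (2.76) or combination mouse 3 (1.71).

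In the tumour cells of the single-cell data SHP099 lowered glycolysis genes. Pgk1, which encodes phosphoglycerate kinase (chromosome X, 106187100 to 106203699), fell from 923 ± 124 to 272 ± 32.7 CPM (SD, n = 3), a log2 fold change of -1.76 ± 0.18 (SE, adjusted p = 6.29e-05). Ldha, which encodes lactate dehydrogenase A, fell from 1599 ± 194 to 609.5 ± 66.0 CPM, or -1.39 ± 0.15 (SE, adjusted p = 0.000101), and Pkm fell (-1.03 ± 0.10 at adjusted p = 3.12e-05). Cxcl5 rose from 57.3 ± 3.27 to 210.0 ± 82.2 CPM, or 1.89 ± 0.30 (SE, adjusted p = 0.0014). Cp, which encodes ceruloplasmin, a copper carrier, rose (2.52 ± 0.30 at adjusted p = 0.000183), as did Muc1, an epithelial mucin gene (1.47 ± 0.21 at adjusted p = 0.000596), and the adhesion gene Vcam1 (1.23 ± 0.20 at adjusted p = 0.00136). The keratin genes Krt7 and Krt19 fell (-3.65 ± 0.65 at adjusted p = 0.00277 and -0.62 ± 0.11 at adjusted p = 0.00242). Spred2 and Dusp6, which are feedback genes of ERK, fell (-0.54 ± 0.16 at adjusted p = 0.0391 and -0.53 ± 0.16 at adjusted p = 0.041). Cxcl1, Cxcl2 and Cxcl3 gave -0.05 ± 0.37 at adjusted p = 0.961, -0.05 ± 0.30 at adjusted p = 0.945 and -0.20 ± 0.33 at adjusted p = 0.737, Cxcr2 gave -0.20 ± 0.31 at adjusted p = 0.723, and Ptpn11 gave -0.30 ± 0.10 at adjusted p = 0.0755. Spred2 lost its call without vehicle mouse 1 (-0.57), vehicle mouse 2 (-0.53), vehicle mouse 3 (-0.52), SHP099 mouse 2 (-0.56) or SHP099 mouse 3 (-0.43). Dusp6 lost its call without vehicle mouse 1, 2 or 3 (-0.58, -0.55, -0.45) or SHP099 mouse 1, 2 or 3 (-0.45, -0.65, -0.50).

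Of 10993 genes tested in tumour cells 686 were higher and 798 lower after SHP099, with 3098 at an unadjusted p under 0.05. Of the 1484, 1454 had groups that did not overlap, against 33.5% of tested genes and 10% by chance. Of 17 glycolysis genes 10 fell, 13 adjusted over the list alone, with a median of -1.03 (camera adjusted p = 7.56e-13, adjusted p = 0.322 with an estimated correlation). Of 10 macrophage genes 7 fell, 9 adjusted over the list alone, with a median of -3.26 (adjusted p = 9.06e-12, adjusted p = 0.322 with an estimated correlation), among them Apoe at -4.47 ± 0.52 at adjusted p = 0.000156. The 19 ERK target genes had 1 higher and 2 lower, against 2 and 3 adjusted over the list alone, and were not called as a list (median -0.10, adjusted p = 0.449). Of 4 CXCR2 ligand genes 1 rose (Cxcl5), also adjusted over the list alone. Their median was -0.05, their mean 0.40 and the camera direction higher, without a call (adjusted p = 0.306).

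The tumour class joins clusters 21 and 23, and their balance differs: cluster 21 took 10.3% of vehicle cells and 0.718% of SHP099 cells, and cluster 23 took 8.02% and 1.71%. In cluster 21 alone Cxcl5 after SHP099 gave 0.34 and lost its call, and in cluster 23 alone it gave 1.83. The 3 SHP099 mice gave 219 tumour cells in all and the vehicle mice 2226. More than 2 neutrophil marker UMIs were found in 50.1% of vehicle tumour cells and 43.8% of SHP099 tumour cells, against 5.66% and 3.32% of B cells, at median depths of 10100 and 14450 UMIs in tumour cells and 926 and 1007 in B cells. In tumour cells with few neutrophil transcripts 694 genes were called after SHP099; Cxcl5 gave 2.17 and Cxcl2 fell, at -1.21. The count was 888 without vehicle mouse 3 and 790 without SHP099 mouse 2.

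SX682 gave 7 higher and 33 lower genes in tumour cells, with 1096 at an unadjusted p under 0.05 and groups that did not overlap for all 40 (18.1% of tested genes, 10% by chance). Fdps, an enzyme gene of cholesterol synthesis, rose from 166 ± 4.00 to 236 ± 11.1 CPM (SD, n = 3), a log2 fold change of 0.51 ± 0.08 (SE, adjusted p = 0.0202). Erh, a small nuclear protein gene, rose from 103 ± 6.45 to 168 ± 9.75 CPM, or 0.70 ± 0.09 (SE, adjusted p = 0.00897). Cxcl5 gave 0.92 ± 0.29 at adjusted p = 0.274, higher in 2 of 3 mice, and did not pass. Cxcl1, Cxcl2 and Cxcl3 gave 0.56 ± 0.33 at adjusted p = 0.634, 0.23 ± 0.30 at adjusted p = 0.878 and -0.09 ± 0.29 at adjusted p = 0.97, Cxcr2 gave 0.20 ± 0.23 at adjusted p = 0.853 and Ptpn11 -0.05 ± 0.09 at adjusted p = 0.918. Of the 4 CXCR2 ligand genes 0 passed over all genes and 1 rose adjusted over the list alone, with a median of 0.40 and no call (adjusted p = 0.192). The 19 ERK target genes had 0 called either way, a median of 0.03 and a mean of -0.01. Of 18 cholesterol genes 1 rose, 2 adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.00672, adjusted p = 0.742 with an estimated correlation). The count was 3, 3 and 22 without vehicle mouse 1, 2 and 3, and 2, 6 and 4 without SX682 mouse 1, 2 and 3, where lower genes no longer led (1 higher and 1 lower, 4 and 2, and 2 and 2). It was 2, both higher, with only these 2 treatments fitted, and 2 among tumour cells with few neutrophil transcripts. Fdps lost its call without vehicle mouse 1 (0.53), vehicle mouse 2 (0.50), SX682 mouse 1 (0.49) or SX682 mouse 3 (0.51). Erh lost its call without vehicle mouse 2 (0.67) or SX682 mouse 1 (0.66).

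After the combination Cxcl5 rose in tumour cells from 57.3 ± 3.27 to 356 ± 75.6 CPM (SD, n = 3), a log2 fold change of 2.64 ± 0.30 (SE, adjusted p = 0.000279). Cxcl1 (chromosome 5, 90891241 to 90893115) rose from 76.6 ± 8.83 to 189 ± 31.3 CPM, or 1.30 ± 0.33 (SE, adjusted p = 0.0257), and Cxcl2 (90903871 to 90905938) rose from 1144 ± 266 to 2783 ± 756 CPM, or 1.28 ± 0.30 (SE, adjusted p = 0.0182). Cxcl3 gave 0.78 ± 0.29 at adjusted p = 0.104. Pgk1 and Ldha fell (-1.85 ± 0.18 at adjusted p = 0.000102 and -1.38 ± 0.15 at adjusted p = 0.000273), as did Bnip3, a mitophagy gene switched on by low oxygen (-2.01 ± 0.43 at adjusted p = 0.0117). Igfbp3, which binds insulin-like growth factors, fell (-1.85 ± 0.21 at adjusted p = 0.000273). Tnf and Tnfaip2, genes of NF-kB signalling, rose (1.32 ± 0.28 at adjusted p = 0.0108 and 0.96 ± 0.20 at adjusted p = 0.0094). Krt18 fell (-1.13 ± 0.18 at adjusted p = 0.00216). Cxcr2 and the chemokine gene Ccl4, which neutrophils express strongly, rose (1.11 ± 0.22 at adjusted p = 0.00802 and 1.85 ± 0.33 at adjusted p = 0.00417). Ptpn11 gave -0.08 ± 0.09 at adjusted p = 0.637. Cxcl1 lost its call without vehicle mouse 1 (1.33), vehicle mouse 2 (1.36), vehicle mouse 3 (1.20), combination mouse 1 (1.18) or combination mouse 2 (1.30). Cxcl2 lost its call without vehicle mouse 2 (1.12), vehicle mouse 3 (1.29), combination mouse 1 (1.25) or combination mouse 3 (1.09).

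Tumour cells of the combination had 523 higher and 612 lower genes than those of vehicle, with 2816 at an unadjusted p under 0.05. Of the 1135, 1126 had groups that did not overlap, against 34.6% of tested genes and 10% by chance. Of 4 CXCR2 ligand genes 3 rose, 4 adjusted over the list alone, with a median of 1.29 (camera adjusted p = 1.73e-05, adjusted p = 0.204 with an estimated correlation). Of 17 glycolysis genes 9 fell, 12 adjusted over the list alone, with a median of -1.06 (adjusted p = 1.42e-14, adjusted p = 0.291 with an estimated correlation). Of 22 NF-kB target genes 6 rose, 10 adjusted over the list alone, with a median of 0.46 (adjusted p = 0.000112, adjusted p = 0.291 with an estimated correlation). The NF-kB list was not tested in tumour cells with few neutrophil transcripts. The 19 ERK target genes had 1 lower, 2 adjusted over the list alone, and were not called (median -0.20, adjusted p = 0.0793). Of 9 neutrophil marker genes 4 rose, against 6 higher and 1 lower adjusted over the list alone, with a median of 1.01 (adjusted p = 0.00122, adjusted p = 0.499 with an estimated correlation). More than 2 neutrophil marker UMIs were found in 62.2% of these tumour cells and 9.74% of B cells of the same pool, at median depths of 7762 and 1001 UMIs. In tumour cells with few neutrophil transcripts 488 genes were called: Cxcl5 gave 2.85 and Cxcl1 1.63 with their calls, Cxcl2 gave 0.10 without, and Ccl4 reversed to -1.11. Cxcl2 also lost its call in cluster 23 alone (1.21), where Cxcl1 gave 1.25 and Cxcl5 2.53. The count was 690, 625 and 579 without vehicle mouse 1, 2 and 3, and 628, 754 and 635 without combination mouse 1, 2 and 3.

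**Figure D4:**
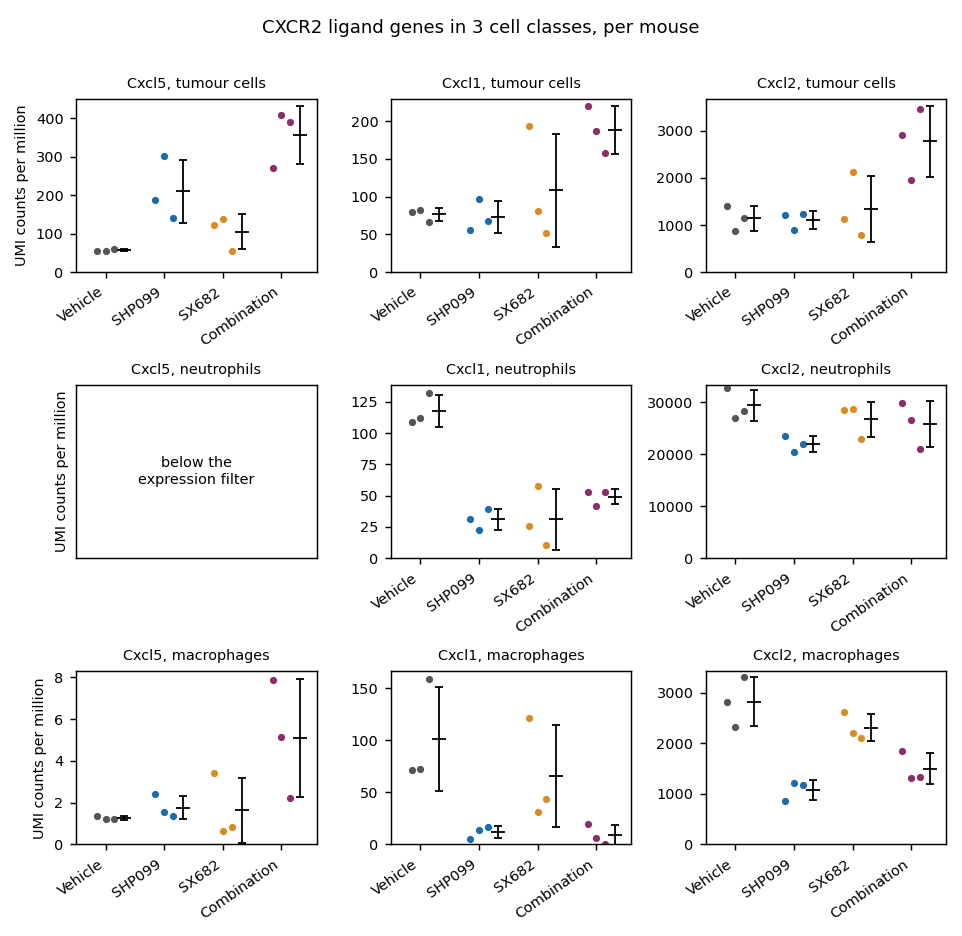
UMI CPM of Cxcl5, Cxcl1 and Cxcl2 in tumour cells, neutrophils and macrophages of each mouse, with points for mice and the dash and bar for the mean ± SD of n = 3. In tumour cells Cxcl5 averages 57.3 in vehicle and 356 in combination mice, and in neutrophils, where Cxcl5 was below the filter, Cxcl1 averages 118 and 49.1.

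Set against SHP099 alone, tumour cells of the combination had 94 higher and 79 lower genes, with 1884 at an unadjusted p under 0.05. Of the 173, 172 had groups that did not overlap, against 20.7% of tested genes and 10% by chance. Tm4sf1, a surface protein gene of carcinoma cells, rose from 276 ± 65.0 to 1172 ± 249 CPM (SD, n = 3), a log2 fold change of 2.09 ± 0.25 (SE, adjusted p = 0.0114). Cdh1, which encodes E-cadherin, fell from 230.0 ± 6.77 to 152 ± 0.272 CPM, or -0.60 ± 0.09 (SE, adjusted p = 0.0168). Cxcl2 rose (1.33 ± 0.31 at adjusted p = 0.0497), while Cxcl1, Cxcl3 and Cxcl5 gave 1.34 ± 0.37 at adjusted p = 0.0786, 0.98 ± 0.33 at adjusted p = 0.145 and 0.75 ± 0.29 at adjusted p = 0.204 and did not pass. Cxcr2 and Tyrobp, genes of myeloid cells, rose (1.31 ± 0.30 at adjusted p = 0.0489 and 1.48 ± 0.27 at adjusted p = 0.0289). Fdps fell (-0.36 ± 0.08 at adjusted p = 0.044), and turned to 0.10 in tumour cells with few transcripts of neutrophils, macrophages, T cells and B cells and to 0.09 in cluster 21 alone. Ptpn11 gave 0.22 ± 0.11 at adjusted p = 0.418. Of the 4 CXCR2 ligand genes 1 rose, 4 adjusted over the list alone, with a median of 1.15 (camera adjusted p = 2.8e-05, adjusted p = 0.151 with an estimated correlation). Of 16 genes of the neutrophil S100 list 4 rose, against 14 higher and 1 lower adjusted over the list alone, with a median of 1.19 (adjusted p = 3.01e-13, adjusted p = 0.151 with an estimated correlation). More than 2 neutrophil marker UMIs were found in 43.8% of SHP099 and 62.2% of combination tumour cells, and S100a8 of that list had 708 and 1476 CPM in all tumour cells but 3.00 and 9.35 CPM in those with few neutrophil transcripts. The count was 91, 1 and 81 without SHP099 mouse 1, 2 and 3 (44, 0 and 34 higher) and 38 and 5 without combination mouse 1 and 3 (16 and 3 higher), so lower genes led in 4 of these 5. It was 6 among tumour cells with few neutrophil transcripts and 0 with equal cell numbers per mouse (815 at an unadjusted p under 0.05). Tm4sf1 lost its call without SHP099 mouse 2 (1.96). Cdh1 lost its call without SHP099 mouse 2 (-0.58) or combination mouse 3 (-0.61). Cxcl2 lost its call without SHP099 mouse 1 (1.39), SHP099 mouse 2 (1.19), SHP099 mouse 3 (1.41), combination mouse 1 (1.29) or combination mouse 3 (1.13). Cxcr2 lost its call without SHP099 mouse 1 (1.37), SHP099 mouse 2 (1.36), SHP099 mouse 3 (1.19), combination mouse 1 (1.43) or combination mouse 3 (1.02). Tyrobp lost its call without SHP099 mouse 2 (1.35), SHP099 mouse 3 (1.45) or combination mouse 3 (1.11). Fdps lost its call without SHP099 mouse 1, 2 or 3 (-0.33, -0.42, -0.34) or combination mouse 1, 2 or 3 (-0.36, -0.38, -0.39).

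The combination was also set against SX682 alone, without fits that leave out mice. This gave 202 higher and 76 lower genes in neutrophils, 115 and 68 in CD8 T cells and 271 and 141 in tumour cells. Among cell classes dendritic cells were lower in the combination (log2 fold change -1.56 ± 0.36, adjusted p = 0.0115), as was the unnamed cluster 27 (-1.36, adjusted p = 0.0424).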

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

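The test of joint capture for keratins and the splits of the samples were chosen before their results were seen, and the other tests in this part after. In 14 of 307 comparisons of 1 gene between a pair of cell types (4.56%), every treated mouse moved 1 way in 1 cell type and the opposite way in the other. The genes are those named above, some for a change in 1 of the types, so no chance rate is given. The differences were not tested, and carried transcripts can mimic them. The scope (tumour cells, neutrophils and CD8 T cells, no macrophages, at least 10 mean CPM) was set after the data were seen. After SHP099, Gzma (2.96 in neutrophils, -5.47 in tumour cells) lay 8.43 apart on the log2 scale, Gbp2 (1.78 and -2.65) 4.43 apart, and Fdps (-0.97 and 0.53) 1.49 apart. After SX682, Fdps (-1.16 in neutrophils, 0.51 in tumour cells) lay 1.67 apart. After the combination, Cxcl1 (1.30 in tumour cells, -1.24 in neutrophils) lay 2.54 apart and Il1r2 (1.40 and -0.09) 1.49 apart. Chil3 (1.76 in CD8 T cells, -2.62 in neutrophils) lay 4.38 apart, S100a9 (1.14 and -0.85) 1.99 apart, and Tcf7 (0.26 in tumour cells, -0.61 in CD8 T cells) 0.87 apart. Between the combination and SHP099, Retnlg (1.5 in tumour cells, -0.77 in neutrophils) lay 2.27 apart, Osm (1.31 and -0.58) 1.90 apart, Sirpa (1.19 and -0.51) 1.70 apart, Krt18 (-0.63 and 1.1) 1.73 apart and Fdps (-0.36 and 0.41) 0.77 apart.

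Alveolar type 2 genes were lower in the SHP099 bulk libraries, sorted for Epcam, which normal lung epithelium also carries. Vehicle tumour cells with few neutrophil transcripts held the 7 called genes at 0.341% of their summed level in vehicle bulk libraries. Clustering sets cells high in these genes apart, so tumour cells lowering them was not decided. Fewer alveolar type 2 cells among the sorted cells may explain the fall but were neither shown nor excluded. For it, 41 other genes specific to those cells had a median log2 fold change of -2.14 (quartiles -3.21 and -1.12, 38 below 0). With a fold against airway cells of 1 or 10 in place of 2.5 the median was -1.91 over 45 genes and -3.03 over 26; the alveolar type 1 and airway lists had medians of -0.30 and -0.40. Against it, alveolar type 2 cells took 2.11 ± 1.34% of these and tumour cells together in vehicle mice of the single-cell data and 15.6 ± 12.2% in SHP099 mice (SD, n = 3), every SHP099 mouse above every vehicle mouse. Single-cell nodules were not sorted for Epcam, so the share in sorted cells is unknown. Lower expression within the remaining alveolar type 2 cells stays open.

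Tumour keratins fell in SHP099 neutrophils by a log2 ratio of -2.64 ± 0.21. Free RNA from fewer tumour cells would lower them alike in other cells, and B, NK and T cells lay -0.27, 0.10 and -0.07 from neutrophils, but alveolar macrophages 2.76, so the test does not decide. Their Krt8 and Krt18 went from 67.9 to 9.87 and 33.8 to 5.85 CPM while Krt19 went from 98.2 to 219 CPM, and the median of the 4 cell types, an earlier form of the test, was 0.01. Neutrophils captured together with tumour cells may add to it: 18% of the keratin UMIs of vehicle neutrophils lay in cells with 10 or more of them (interval 6.76 to 28.1), against a bound of 20% set before, and the rule that a value within its spread decides nothing was added after. Capture in 1 pool per treatment keeps both open.

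Neutrophil transcripts in tumour cells were not explained by random doublets: their excess was 4.80, 2.49, 5.23 and 3.79 times that of macrophage transcripts in the vehicle, SHP099, SX682 and combination pools, the lowest 2.49. Free RNA from neutrophils was excluded too, as tumour cells held 14.7, 21.2, 12.2 and 10.4 times the neutrophil UMIs of B cells. Against tumour cells making them, the sorted vehicle bulk libraries held the markers at 2.16% of their level in vehicle tumour cells. This does not exclude it, because bulk reads and UMIs weigh short and long transcripts differently and the bulk cells were sorted for Epcam. Joint capture of neutrophils bound to tumour cells was not tested and stays open.

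With 3 samples against 3 there are 10 splits, too few for a share under 0.05. Bulk gave 23 genes against 0 in the highest other split, and neutrophils 977 against 1, 38 against 1, 482 against 0 and 88 against 4 (SHP099, SX682 and combination against vehicle, then combination against SHP099). CD8 T cells gave 438 against 1, 17 against 3, 217 against 2 and 68 against 5. Tumour cells gave 1484 against 0, 40 against 42, 1135 against 0 and 173 against 0, so for SX682 2 splits gave at least 40 genes and elsewhere 1.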

How the results depend on the processing

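Parts of the tumour class, free RNA genes, genes of the alveolar and airway cluster left out, and 33 clusters in place of classes were tests chosen only after the result was seen. Over the planned and added settings that leave no sample out, 66 counts stayed within 1.5 times and 53 moved; when 1 library or mouse was left out, 49 stayed and 65 moved. For named genes, 1914 values kept direction and side of the threshold, 290 lost and 58 gained a call and 3 reversed under the former; 1364 were kept, 394 lost and 12 gained under the latter. Of 222 called genes 106 kept the call without each mouse or library and 116 did not. For shares, 623 values were kept, 43 lost and 6 gained when a mouse was left out.

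Leaving out 1 sample gave 0 to 16 genes in bulk. Neutrophils gave 548 to 820 genes (SHP099 against vehicle), 12 to 42 (SX682), 216 to 427 (combination) and 42 to 59 (combination against SHP099). CD8 T cells gave 250 to 327, 1 to 22, 70 to 206 and 27 to 73, and tumour cells 790 to 1328, 2 to 22, 579 to 754 and 1 to 209 in the same order. Classes with a changed share ran from 2 to 8, neutrophil clusters from 1 to 4 and T cell clusters from 0 to 1.

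Under DESeq2 the counts were 569 in bulk (69 higher, 500 lower), 644 and 68 in neutrophils after SHP099 and SX682, 33 and 103 in CD8 T cells after SX682 and against SHP099, and 166 and 472 in tumour cells for the same contrasts. Without a filter on low counts they were 283 in bulk (25 higher), 137 and 282 in neutrophils after SX682 and against SHP099, 71, 343 and 197 in CD8 T cells after SX682, the combination and against SHP099, and 217 and 665 in tumour cells after SX682 and against SHP099. With only the treatments compared, SX682 gave 24 genes in neutrophils and 2 in tumour cells, both higher. The number in the labels does not pair mice (median correlation of equal numbers 0.057 in bulk, -0.036 in neutrophils, 0.019 in CD8 T cells and 0.033 in tumour cells); as a block it gave 151 genes in CD8 T cells against SHP099, 16 and 115 in tumour cells after SX682 and against SHP099, and 0 T cell clusters. The cause of these shifts was not tested.

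With equal cell numbers per mouse, which leaves fewer UMIs, neutrophils gave 238, 6, 126 and 3 genes in the order above, CD8 T cells 235, 8, 105 and 58, and tumour cells 366, 0, 117 and 0 by edgeR (635 and 815 at an unadjusted p under 0.05 for the counts of 0, where DESeq2 on all cells gave 166 and 472). Without genes that free RNA could supply, neutrophils gave 18 genes after SX682 and 11 against SHP099, and CD8 T cells 11 after SX682. Without alveolar and airway genes bulk gave 2.

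Tumour cells with few neutrophil transcripts gave 694, 2, 488 and 6 genes, and those with few neutrophil, macrophage, T and B cell transcripts 393, 0 (464 at an unadjusted p under 0.05, edgeR), 190 and 3. Cluster 21 alone gave 509 genes after SHP099, 2 after SX682 and 26 against SHP099, and cluster 23 alone 70 after SX682. Reversed were Ccl4 after the combination (-1.11 with few neutrophil transcripts) and Fdps against SHP099 (0.10 with few transcripts of the 4 other cell types, 0.09 in cluster 21). For shares, limma on arcsine square root values gave 6 classes and 2 T cell clusters, and the 33 clusters gave 12. Camera called 153 of 481 list tests, 7 with an estimated correlation, and fry 56. Depth limits what each mouse can show, with as few as 57 tumour cells.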

Other observations

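Macrophages, whose genes were looked at after the data were seen, changed more genes after SHP099 than neutrophils or CD8 T cells did in count: 1958 of 10862 by edgeR, against 135 after SX682 and 1236 after the combination. Arg1, the arginase gene of suppressive macrophages (chromosome 10, 24915221 to 24927484), had 73.4 CPM in SHP099 and 818 CPM in vehicle mice (log2 fold change -3.48 ± 0.41, adjusted p = 6.59e-05), and -3.61 after the combination (adjusted p = 0.000129). The acute phase gene Saa3 gave -4.48 ± 0.78 (adjusted p = 0.00123) and -4.66. Cxcl1 gave -3.09 ± 0.68 (adjusted p = 0.00572) and -3.63 (adjusted p = 0.00419), and Cxcl2 -1.38 ± 0.17 (adjusted p = 7.51e-05) and -0.91 (adjusted p = 0.00228). Igf1, a growth factor gene of resident macrophages, gave 1.89 ± 0.15 (adjusted p = 5.03e-06) and 1.90. Cluster 16, defined by Arg1, Pf4 and Saa3, took 8.32% of cells in vehicle, 0.327% in SHP099, 3.11% in SX682 and 0.350% in combination mice (exact permutation adjusted p = 0.0157), so its loss and these gene changes in the class are not separate observations. All 3 treated mice lay beyond all 3 vehicle mice for each of these genes in both comparisons. No mouse was left out in these fits.

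In a look also taken after the data were seen, vehicle tumour cells expressed Hnf4a (71.6 CPM) and Cdx2 (76.8 CPM), regulators of gut epithelium, and the gut genes Lypd8 (638 CPM) and Alpi (173 CPM), with 214, 84.2, 233 and 271 CPM in vehicle bulk libraries. The lung regulator Nkx2-1 was at 0.235 CPM in these cells. Across 10676 genes, which are not independent, the SHP099 log2 fold changes of bulk and single-cell tumour cells had r = 0.251 and rho = 0.232.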
